A study of Mus musculus with 9 samples.

How the data were processed

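Total RNA was measured in 9 samples of AML12 cells, 3 each of untreated cells, cells given PA and OA, and cells given Ang(1-7) before PA and OA. RNA was extracted with Qiazol and an miRNeasy kit, per the labels' protocols. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels' group and replicate number were used for each sample, and every column of sample values was matched to 1 sample by its name.

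The authors deposited 3 tables, 1 for each pair of groups, with whole-number counts of reads per RefSeq transcript for the 6 samples of the pair. The tools were bcl2fastq, HISAT2 2.2.5 and HTSeq 0.11.2, per the submitters' processing notes. The notes name a human genome build, whereas the tables hold mouse transcripts, so no coordinates are given here, and the annotation release and counting options are not given in the sources used here. A sample had the same counts in each table that held it. The tables listed 6936 transcripts (6213 gene symbols) for PA/OA against control, 14553 (10259) for Ang(1-7) against PA/OA and 6828 (6141) for Ang(1-7) against control, and 6674 transcripts were in all 3. The lowest mean count of a listed transcript was 56.8, 5.17 and 59.5, so the table of both fatty acid groups reached lower levels than those with controls. Curated transcripts numbered 5403, 8076 and 5357 and predicted ones 1533, 6477 and 1471. Genes with several listed transcripts numbered 651, 3096 and 619, and the level of a gene can differ between tables because other transcripts of it are listed, as for Cpt1a (1, 4 and 1) and Plin2 (1, 3 and 1).

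The authors' deposited tables also give a log2 fold change and an unadjusted p-value per transcript, with no test named in the file headers. The deposited log2 fold change followed from the counts with 1 factor per sample, with a largest difference of 0.0292, 0.000549 and 0.0207 in transcripts with a mean above 500 counts. In the authors' deposited tables, 1617, 976 and 1431 transcripts had a p-value under 0.05. With a Benjamini-Hochberg adjustment of the authors' deposited p-values, made here, 782 (344 higher), 11 (7 higher) and 534 (286 higher) passed 0.05. The results given here rest on the counts, not on those columns.

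Counts of the listed transcripts were summed per gene symbol. Genes were tested within the table of each pair with edgeR 4.0.16 in R 4.3.3 (trimmed mean of M values, filterByExpr, quasi-likelihood F test), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, 6213, 9261 and 6134, with a threshold of 0.05. The replicate number was not a term of the model. The estimated biological coefficient of variation was 22.4%, 44.3% and 30.7%. Levels are CPM, counts scaled to a common library total, with trimmed mean scaling (mean ± SD, n = 3 per group), without it for summed marker genes, fold changes are given as log2 with the standard error of the model, and 95% intervals of summed counts are exact Poisson intervals. Reads without molecular identifiers are not independent molecules, so such intervals cover counting error only.

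Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2) where at least 5 members were measured, with Benjamini-Hochberg adjustment over the lists of a comparison. The 27 lists held 681 genes: lipid droplet, fatty acid oxidation, lipogenesis, cholesterol, sterol efflux, unfolded protein response, integrated stress response, antioxidant, inflammation, interferon, autophagy, renin-angiotensin, apoptosis and p53, cell cycle, hepatocyte identity, glucose and insulin, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, heat shock, immediate early, extracellular matrix and TGF-beta, and markers of stellate cells, macrophages, endothelial cells and cholangiocytes. Camera with an estimated correlation and fry were run beside it. A count adjusted over the list alone repeats the Benjamini-Hochberg adjustment on the members only.

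The groups, tests, lists, named-gene rule and most alternatives were chosen before the data were examined. The rule named, per comparison, up to 8 genes with the largest rise and 8 with the largest fall among called genes with a mean of at least 50 counts and groups that did not overlap, leaving out unnamed gene models (3 of those were called in PA/OA against control). It also named up to 3 members of lowest p of each list that passed and of the lipid droplet, fatty acid oxidation, lipogenesis, cholesterol and renin-angiotensin lists, and always Plin2, Cpt1a, Pdk4, Angptl4, Scd1, Hmgcs1, Ddit3 and Mas1. Some genes that the rule named are not reported here. Genes named outside the rule are said to be so where they appear. Lists of nervous system and blood markers, complement, retinoid and histone genes were added after the data were seen.

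The alternatives were a fit with the replicate number as a block, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a mean of at least 50 counts, a log2 change of at least 1, an adjusted p under 0.01, all 9 samples in 1 fit, genes listed in all 3 tables, and each library left out in turn. Added after the data were seen were transcripts tested without summing, limma-voom with library quality weights, a correction for transcript length and GC content, Ang(1-7) 1 as the 1 treated library, and the nervous system and blood markers left out. Transcripts were matched to a RefSeq gene table of GRCm38.p6 for names and the number of transcripts per gene, and 12534 of 14554 (86.1%) matched. Length and GC content were those of the longest GENCODE transcript with the gene's symbol, which need not be the transcript counted. The offsets of the length and GC correction were centred per library after a version without centring was seen to change the scaling.

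The tests were checked on simulated counts made from the means, library sizes and spread of these samples with 200 genes changed. A gene had the same spread in both groups, and the changed genes were drawn from those with a mean of at least 50 counts. Of genes changed 1.5-fold, 2-fold and 4-fold, 41.8%, 64.2% and 92.4% were recovered for PA/OA against control (5 false calls among 6213 genes), 8.96%, 31.3% and 74.2% for Ang(1-7) against PA/OA (10 among 8814) and 13.4%, 32.8% and 84.8% for Ang(1-7) against control (3 among 6134). With no change simulated, 0, 0 and 2 genes and 0 lists were called, and a list shifted by 0.5 log2 was recovered in each comparison with 0 other lists. Overlaps and correlations between comparisons that share libraries were set beside 40 simulated data sets with the same sharing.

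Some limits follow from how the tables were made. Genes with near-identical copies or processed pseudogenes, such as histone and ribosomal protein genes, are uncertain because the treatment of reads that map to several places is not given in the sources used here, and overlapping and antisense genes are uncertain because the use of strand is not given either. Genes with several RefSeq transcripts had lower listed counts: the median was 61.8 CPM with 1 transcript, 9.86 with 2, 3.58 with 3 to 4 and 1.85 with 5 or more. For ribosomal protein genes these medians were 3610, 113, 192 and 36.2 CPM, so a level cannot be compared between genes and a low level is not low expression. The libraries held 24759184 to 28704499 listed counts each, so counting error was small for most listed genes and the spread between samples set the precision.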

Results

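RNA was sequenced from AML12 cells, a mouse hepatocyte line, in 3 groups of 3 samples. Control cells received no treatment. The PA/OA group was exposed to 0.2 mM PA and 0.4 mM OA, read here as palmitic and oleic acid, for 24 h as a model of fat accumulation in hepatocytes. The Ang(1-7) group received 100 nM Ang(1-7), a peptide of the renin-angiotensin system, 30 min before the same fatty acids. The listed counts came to 27357654, 27130285 and 26576151 in controls 1 to 3, 26033617, 25088211 and 25592878 in PA/OA 1 to 3, and 24759184, 28704499 and 26177572 in Ang(1-7) 1 to 3. Each pair of groups had its own table of counts per RefSeq transcript, and counts were summed per gene symbol. Samples of the same group differed by more than counting noise, with a chi-square per degree of freedom of 18.4 to 31.6 in pairs without Ang(1-7) 2. No library was therefore treated as a second sequencing of another, but this does not show that the samples came from separate cultures.

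Ang(1-7) 2 stood apart from the other 8 libraries. Its log2 counts correlated with theirs at r = 0.917 to 0.937 across genes, which are not independent replicates, whereas the lowest r among the others was 0.969. Its chi-square per degree of freedom was 222 against Ang(1-7) 1 and 208 against Ang(1-7) 3. Of the transcripts of the table of both fatty acid groups, 2664 had a count of 0 in this library and 576 to 1439 in the other 5. Eef1a1, a translation elongation factor, took 5.45% of its counts and 4.61% to 4.94% elsewhere.

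Transcripts of the nervous system were present in Ang(1-7) 2 and 3. The neurofilament gene Nefl had 923 and 477 counts there and 0 in Ang(1-7) 1 and in each PA/OA library, and Gfap, an astrocyte filament gene, had 888 and 378 counts against 12 and 0. A list of 35 markers of neurons, astrocytes and oligodendrocytes, drawn up after such genes were seen, had 28 members listed, of which 5 to 7 had a count above 0 in the PA/OA libraries. Their counts summed to 216 CPM (exact 95% Poisson interval 210 to 221) in Ang(1-7) 2 and 119 (115 to 123) in Ang(1-7) 3, against 6.06 (5.13 to 7.11) in Ang(1-7) 1 and 3.11 to 4.07 in PA/OA. The hemoglobin genes Hba-a1 and Hbb-bs summed to 4.01 and 2.44 CPM in Ang(1-7) 2 and 3 and to 0 to 0.159 in the other 4 libraries. Stellate cell and fibroblast markers, a sum without Gfap, came to 25.3 and 18.3 CPM in Ang(1-7) 2 and 3 and to 7.73 to 9.76 in the others. All 7 listed members had a count above 0 in Ang(1-7) 2 and 3, and 2 or 3 of them did in the others. Macrophage markers lay between 671 and 812 CPM in the 6 libraries and endothelial markers between 1.71 and 3.84. Of the 6 listed macrophage markers, all 6 had a count above 0 in Ang(1-7) 2 and 3, and 4 did in each of the others. Cholangiocyte markers reached 1143 in Ang(1-7) 2 and 1567 to 1718 in the others, and hepatocyte markers ranged from 20971 to 23716. These values, like the intervals, cover counting error only.

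**Figure D1:**
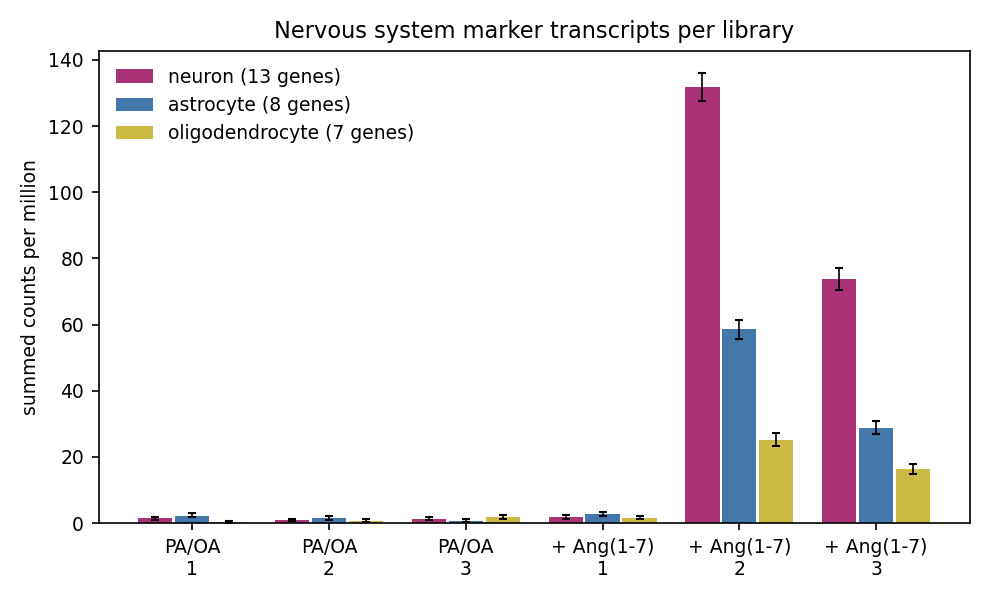
Summed CPM of neuron (13 genes), astrocyte (8) and oligodendrocyte (7) markers in each of the 3 PA/OA and 3 Ang(1-7) libraries, as bars from 0 with exact 95% Poisson intervals. Neuron markers reached 132 and 73.8, astrocyte markers 58.6 and 28.9, and oligodendrocyte markers 25.3 and 16.3 CPM in Ang(1-7) 2 and 3.

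The comparison of PA/OA with control asked how cells given the fatty acids differed from untreated ones. No group received a carrier alone, so the fatty acids cannot be told apart from a carrier or handling that came with them. Changes and effects called those of the fatty acids here and below would include these. Chemokine and acute phase transcripts rose most. Cxcl5, which attracts neutrophils, went from 240 ± 9.79 to 1629 ± 104 CPM (mean ± SD, n = 3 per group), a 6.79-fold rise, and C3, the central complement component, rose 4.70-fold from 45.9 ± 2.07 to 216 ± 18.1. Genes of fatty acid use that rose included Cpt1a, which commits fatty acids to mitochondrial oxidation, and the acyl-CoA thioesterase genes Acot1 and Acot2. Ttr, the thyroid hormone carrier transthyretin, fell by 1.79 and Aqp1, a water channel, by 1.67 on the log2 scale. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 314 of 6213 genes changed, 175 higher and 139 lower, with a median log2 change of 0.49 and −0.36. Of them, 28 rose and 5 fell at least 2-fold, and 32 of the lower ones were histone genes (8 without control 1, 20 without PA/OA 2 and 8 without PA/OA 3). An unadjusted p under 0.05 was found for 1204 genes where chance gives 311, and the groups did not overlap in 23.8% of genes where chance gives 10%. The count was 99 without control 1, 200 without control 3, 147 without PA/OA 2 and 134 without PA/OA 3, DESeq2 called 533 genes (278 higher), and a fit of all 9 samples called 31 (29 higher). Of the 38 called genes named by the rule, 20 were called with each of the 6 libraries left out.

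Of 19 measured genes of the list of NF-kB targets, cytokines and acute phase proteins, 7 rose, 0 fell and 12 were not called in edgeR's test. Adjusted over the list alone, 10 rose and 1 fell. The list rose against other genes in camera (median log2 change 0.83, adjusted p = 9.22e-08, adjusted p = 0.117 with an estimated correlation). Log2 changes with their SE were 2.76 ± 0.07 for Cxcl5 (adjusted p = 4.93e-17), 1.65 ± 0.08 for Cxcl1, another neutrophil chemokine (adjusted p = 1.33e-11), 1.97 ± 0.23 for Ccl7 and 0.83 ± 0.07 for Ccl2, which both attract monocytes. Cxcl3, a chemokine outside the list, rose by 2.11 ± 0.14. Ptgs2, the inducible cyclooxygenase, rose by 0.79 ± 0.07 and was named after its values were seen. The acute phase gene Saa3 rose from 0.958 ± 0.807 to 21.1 ± 0.777 CPM, a log2 change of 4.47 ± 0.46 (adjusted p = 2.93e-06). Lcn2, which encodes the iron-sequestering lipocalin 2, had 6, 0 and 1 counts in the controls and 273, 106 and 82 in PA/OA (log2 change 6.09 ± 0.83, adjusted p = 0.000106). The log2 change of Lcn2 was 8.30 without control 1, 5.50 without control 2 and 5.38 without PA/OA 1, and that of Saa3 was 5.25 without control 3. Interferon-stimulated genes (3 measured) and macrophage markers (3 measured) had 0 called in edgeR's test, with 0 and 1 adjusted over the list alone, and were too few for camera.

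Of 19 measured genes of fatty acid oxidation and PPAR-alpha targets, 5 rose and 0 fell, and 7 rose adjusted over the list alone. The list rose in camera (median log2 change 0.16, adjusted p = 0.0109, adjusted p = 0.190 with an estimated correlation). Acot1 rose from 143 ± 5.81 to 273 ± 11.6 CPM, a log2 change of 0.94 ± 0.08 (adjusted p = 1.35e-07), and Acot2 rose by 0.99 ± 0.17 (adjusted p = 0.00106). Slc25a20, the mitochondrial carnitine-acylcarnitine carrier, rose by 0.53 ± 0.13 (adjusted p = 0.0207). Cpt1a, listed in this table through 1 transcript, rose from 1.26 ± 0.211 to 4.26 ± 0.738 CPM (log2 change 1.75 ± 0.49, adjusted p = 0.0439). Ucp2, a mitochondrial uncoupling protein gene named after its values were seen, rose by 1.11 ± 0.31 (adjusted p = 0.0439). Angptl4, a lipoprotein lipase inhibitor and PPAR target, was not called (0.24 ± 0.11, adjusted p = 0.242). Without PA/OA 1 the list was not called (adjusted p = 0.0702, range 0.00476 to 0.0702 over the libraries left out). Cpt1a was not called without any of the 6 libraries (adjusted p = 0.145, 0.0794 and 0.0944 without controls 1 to 3, and 0.0883, 0.163 and 0.0864 without PA/OA 1 to 3) nor in limma-voom (0.0626), and Slc25a20 was not called without control 2 (0.0832), control 3 (0.0944) or PA/OA 3 (0.0855). Ucp2 kept its call only without control 3, with an adjusted p of 0.0562 to 0.207 without the other libraries in turn.

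Of 11 measured genes of the lipid droplet and triglyceride storage list, Plin2 rose, 0 fell and 10 were not called in edgeR's test, with 3 risen adjusted over the list alone. Plin2, which encodes a coat protein of lipid droplets and was listed through 1 predicted transcript, went from 3.78 ± 0.856 to 9.28 ± 2.65 CPM (log2 change 1.30 ± 0.35, adjusted p = 0.0386). Hilpda, another droplet protein gene (0.66 ± 0.19, adjusted p = 0.0534), and Dgat2, an enzyme of triglyceride synthesis (0.39 ± 0.14, adjusted p = 0.113), were not called. The list's median log2 change was 0.39, with a camera adjusted p = 0.106 and adjusted p = 0.460 with an estimated correlation. It passed without control 3 alone (adjusted p = 0.0319, range 0.0319 to 0.353 over the libraries left out). The Plin2 call ended without any of the 6 libraries (adjusted p = 0.0988, 0.0705 and 0.112 without controls 1 to 3, and 0.154, 0.0611 and 0.0864 without PA/OA 1 to 3), and DESeq2 called Hilpda (0.0206).

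**Figure D2:**
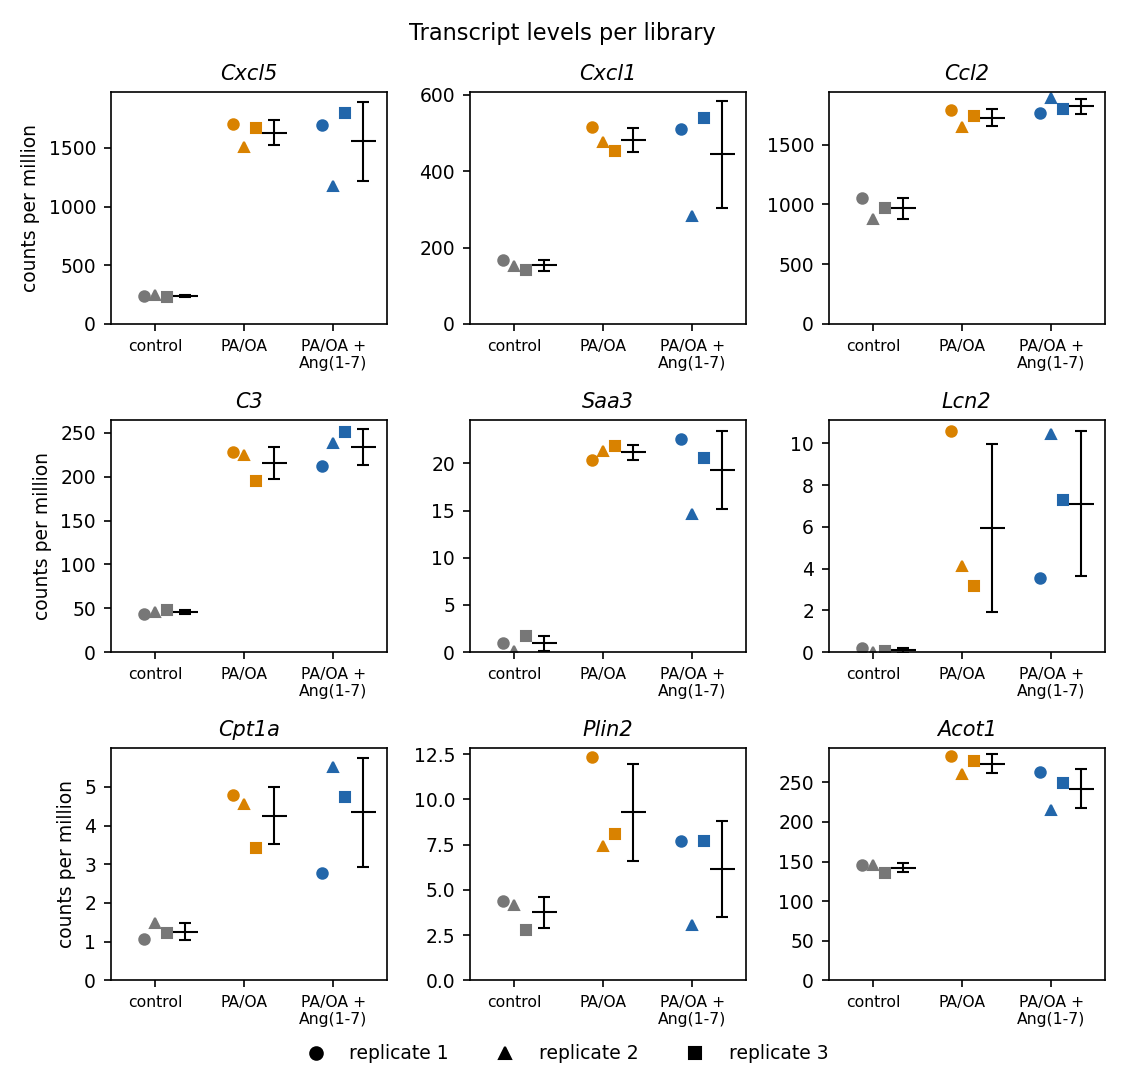
CPM, from 0, of 9 genes in control, PA/OA and Ang(1-7) libraries, 1 point per library with a symbol for each replicate number, and bars for the mean ± SD (n = 3). Cxcl5 lay near 240 in control and 1629 in PA/OA, and Plin2 and Cpt1a are drawn from the transcripts with a value in all 9 libraries.

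Of 19 measured genes of the extracellular matrix and TGF-beta/YAP list, 6 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (median 0.20, camera adjusted p = 0.00131, adjusted p = 0.190 with an estimated correlation). Among those that rose, the YAP targets Cyr61 and Ankrd1 changed by 0.46 ± 0.07 and 0.28 ± 0.05. Vim, the intermediate filament gene vimentin, fell by 0.23 on the log2 scale and was named after its values were seen. The 1 measured stellate cell marker was not called, though it rose adjusted over the list alone. Among 20 immediate early genes, 3 rose and 0 fell, with 5 risen adjusted over the list alone (median 0.21, camera adjusted p = 0.0234, adjusted p = 0.399 with an estimated correlation). These were Ier3 (0.70 ± 0.08) and the transcription factor genes Fosl2 (0.54 ± 0.11) and Klf6 (0.33 ± 0.07). The immediate early list was not called by fry (adjusted p = 0.0672) or, in camera, without control 1 (adjusted p = 0.0823) or PA/OA 1 (0.299, range 0.00383 to 0.299 over the libraries left out). Fosl2 was not called without control 1 (0.0555), nor Klf6 without PA/OA 3 (0.0546), nor Vim without control 2 (0.0510), control 3 (0.117), PA/OA 2 (0.0773) or PA/OA 3 (0.0747).

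Cytosolic ribosomal protein genes fell by small amounts. Of 29 measured, 10 fell, 0 rose and 19 were not called, and 17 fell adjusted over the list alone (median −0.15, camera adjusted p = 3.99e-07, adjusted p = 0.295 with an estimated correlation). Rpl8 fell by 0.26 ± 0.05 on the log2 scale (adjusted p = 0.00251), and Rps3 by 0.21 ± 0.05 (0.0168). Rps19 fell by 0.65 ± 0.15 (0.0163). Of 31 measured nuclear genes of oxidative phosphorylation, 5 fell and 0 rose, and 10 fell adjusted over the list alone (median −0.18, camera adjusted p = 7.12e-07, adjusted p = 0.190 with an estimated correlation). They were Cox7a2 (−0.36 ± 0.08), a cytochrome oxidase subunit, the ATP synthase genes Atp5a1 (−0.19 ± 0.05) and Atp5b (−0.20 ± 0.05), and Cycs (−0.23 ± 0.06) and Ndufb10 (−0.30 ± 0.09), named after their values were seen. With a correction for transcript length and GC content, chosen after the data were seen, the medians were −0.05 and −0.08 and the called genes 5 and 1, while both lists still passed (adjusted p = 0.0227 and 0.00501). Rps3 was not called without control 1 (adjusted p = 0.111) or control 3 (0.10), Rps19 without control 1 (0.136) or PA/OA 3 (0.0855), Atp5b without control 1 (0.120), control 3 (0.0857) or PA/OA 2 (0.0773), and Atp5a1 in any fit but that without PA/OA 1 (0.126, 0.0544 and 0.103 without controls 1 to 3, and 0.101 and 0.0787 without PA/OA 2 and 3). Cycs and Ndufb10 likewise kept their calls without PA/OA 1 alone, with 0.0763 to 0.126 and 0.0815 to 0.162 without the other libraries.

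Among the genes that fell most, Ttr went from 13.4 ± 4.11 to 3.88 ± 1.24 CPM (adjusted p = 0.00357) and Aqp1 from 28.8 ± 9.49 to 9.04 ± 1.65 (adjusted p = 0.000300). Sult1d1, a sulfotransferase gene, fell by 1.44 ± 0.33 on the log2 scale, and Arhgap40 by 1.35 ± 0.38. S100a7a fell by 0.98 ± 0.23, Tmem252 by 0.90 ± 0.23 and Ranbp3l by 0.90 ± 0.12. Of 12 measured hepatocyte identity genes, Ttr fell and Trf, the iron carrier transferrin, rose by 0.41 ± 0.08, 10 were not called, and the counts were the same adjusted over the list alone (median −0.13, camera adjusted p = 0.106). Of 6 cholangiocyte markers, the keratin genes Krt19 (−0.56 ± 0.07) and Krt7 (−0.27 ± 0.06) fell, also adjusted over the list alone, although the list's median was 0.32 and its mean 0.31 (camera direction lower, adjusted p = 0.785). Trf, Krt19 and Krt7 were named after their values were seen. Calls were lost without control 1 for Sult1d1 (0.0740), Arhgap40 (0.105), S100a7a (0.0599) and Tmem252 (0.120), and without control 2 for Arhgap40 (0.125), S100a7a (0.0846) and Tmem252 (0.105). They were also lost without control 3 for Arhgap40 (0.0973), without PA/OA 1 for Arhgap40 (0.0533), without PA/OA 2 for S100a7a (0.0642) and Tmem252 (0.101), and without PA/OA 3 for Sult1d1 (0.0650), Arhgap40 (0.164), S100a7a (0.0747) and Tmem252 (0.0917). Krt7 was not called without control 1 (0.0744), control 2 (0.0513), PA/OA 2 (0.0822) or PA/OA 3 (0.0680).

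Lipid synthesis genes moved both ways. Of 19 genes of fatty acid synthesis and desaturation, the stearoyl-CoA desaturase genes Scd1 (888 ± 52.0 to 693 ± 14.7 CPM, log2 change −0.36 ± 0.06, adjusted p = 0.00177) and Scd2 (−0.23 ± 0.05, adjusted p = 0.0113) fell and Fasn, the fatty acid synthase, rose (0.19 ± 0.05, adjusted p = 0.0458), the same counts as adjusted over the list alone (median −0.15, camera adjusted p = 0.377). Of 20 genes of cholesterol synthesis and uptake, Insig1, which restrains sterol synthesis, fell (−0.35 ± 0.07, adjusted p = 0.00838) and 1 rose, again the same adjusted over the list alone (median 0.07, camera adjusted p = 0.764). Pmvk (−0.59 ± 0.21, adjusted p = 0.107) was not called. Hmgcs1, an early enzyme of sterol synthesis, was not called either (0.22 ± 0.46, adjusted p = 0.861), and its sign turned without control 1 (−0.03) or PA/OA 3 (−0.07). Scd2 was not called without control 2 (0.0612) or PA/OA 3 (0.0576), nor Insig1 without control 1 (0.0634). Fasn was not called without control 1 (0.150), control 2 (0.116), control 3 (0.122), PA/OA 1 (0.0930) or PA/OA 2 (0.184), nor with DESeq2 size factors (0.0566), while DESeq2 called Pmvk (0.0385). Of the 4 measured genes of sterol efflux and lipoproteins, Apob, the apolipoprotein of very low density lipoprotein, rose by 1.00 ± 0.09, also adjusted over the list alone, and was named after its values were seen.

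Stress, signalling and cycle lists had few called genes and none passed camera, and the members named here for them were chosen after their values were seen unless the rule named them. Fry, which does not compare a list with other genes, passed 6 lists in this comparison, of which 5 passed camera: it passed the unfolded protein response list (adjusted p = 0.00698) and not the immediate early list. Of 19 endoplasmic reticulum chaperone and unfolded protein response genes, Dnajc3 rose (0.27 ± 0.08) and 0 fell, with 5 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.174). Of 20 genes of the integrated stress response, Phgdh, of serine synthesis, fell (−0.18 ± 0.05), also adjusted over the list alone (camera adjusted p = 0.455), and Ddit3, the transcription factor CHOP, was not called (−0.14 ± 0.32, adjusted p = 0.876, and 0.07 without PA/OA 3). Hmox1, heme oxygenase, rose among 22 antioxidant genes (0.45 ± 0.12, camera adjusted p = 0.672) and Ctsl, a lysosomal protease, among 24 genes of autophagy and lysosome (0.85 ± 0.24, camera adjusted p = 0.174), with 1 and 0 called adjusted over the list alone. Of 20 apoptosis and p53 genes, Pmaip1 (0.36 ± 0.09) and Bcl2 (0.60 ± 0.15), which promote and restrain apoptosis, rose, with 2 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.456). Foxm1, a transcription factor of the cycle, rose among 22 cell cycle genes (0.41 ± 0.12, camera adjusted p = 0.718, 1 adjusted over the list alone). Irs2 and Sik1, of insulin and kinase signalling, rose among 10 glucose and insulin genes (0.48 ± 0.09 and 0.35 ± 0.08), with 2 risen and 1 fallen adjusted over the list alone (median 0.03, mean −0.01, camera direction higher, adjusted p = 0.694). Bhlhe40 rose among 14 genes of glycolysis and hypoxia (0.33 ± 0.08, camera adjusted p = 0.764, 2 adjusted over the list alone), and Hspe1, a mitochondrial chaperonin, fell among 14 heat shock genes (−0.38 ± 0.07, 1 adjusted over the list alone, median −0.02, mean 0.03, camera direction lower, adjusted p = 0.629). With libraries left out in turn, Irs2 and Hspe1 kept their calls each time and Dnajc3 in no fit (adjusted p = 0.0517 to 0.189). Phgdh kept its call only without PA/OA 1 (0.121 to 0.182 in the other fits), Hmox1 only without control 1 (0.0537 to 0.109), Ctsl only without control 3 (0.0562 to 0.242), Foxm1 only without control 2 (0.0591 to 0.249) and Bcl2 only without control 1 or PA/OA 1 (0.0601 to 0.0848). Pmaip1 lost its call without control 1 (0.112), control 2 (0.0602) or PA/OA 3 (0.0745), Sik1 without control 1 (0.0874) or PA/OA 1 (0.0520), and Bhlhe40 without control 1 (0.105).

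Of 7 measured genes of the renin-angiotensin system, the system that Ang(1-7) belongs to, 0 were called in edgeR's test and 1 fell adjusted over the list alone (median 0.07, camera adjusted p = 0.806). Agt, the precursor angiotensinogen, was at 5.98 ± 1.70 CPM in PA/OA and 3.5 ± 2.45 in control (0.77 ± 0.47, adjusted p = 0.406, and 1.51 without control 2). The peptidase genes Lnpep (0.25 ± 0.14, adjusted p = 0.325) and Thop1 (−0.24 ± 0.07, adjusted p = 0.0626) were not called, but were without PA/OA 1 (adjusted p = 0.0342 and 0.0268, ranges 0.0342 to 0.997 and 0.0268 to 0.217 over the libraries left out). The log2 change of Lnpep was 0.42 without PA/OA 1 and 0.0030 without PA/OA 2, and DESeq2 called Thop1 (0.0182). Mas1, which encodes a receptor of Ang(1-7), was not among the genes of the 3 tables used here, and Pdk4 was listed only in the table of both fatty acid groups. Mitochondrially encoded transcripts and endothelial markers had 0 measured members in this comparison.

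**Figure D3:**
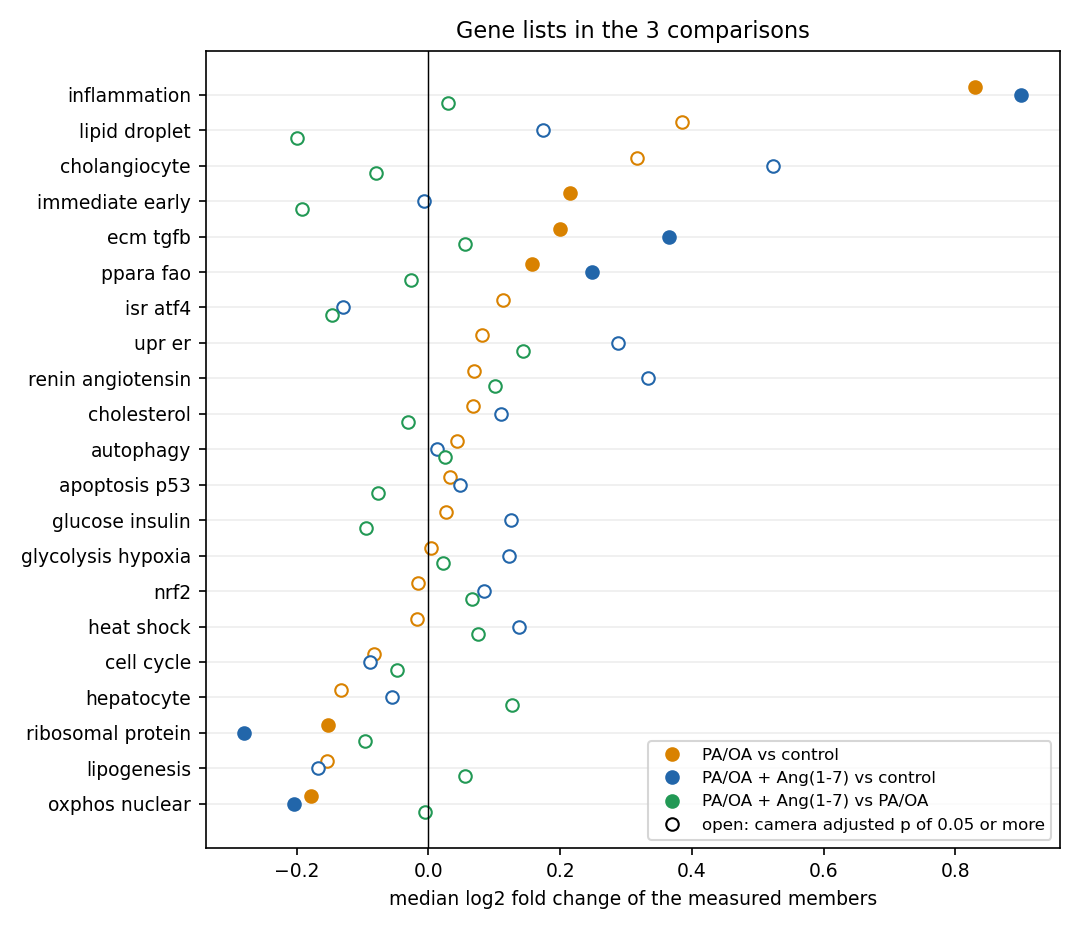
Median log2 fold change (x axis) of the measured members of 21 gene lists (y axis) in the 3 comparisons. Filled points mark a camera adjusted p under 0.05 and open points one of 0.05 or more, with 6 filled for PA/OA against control, 0 for Ang(1-7) against PA/OA and 5 for Ang(1-7) against control.

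The comparison of Ang(1-7) with PA/OA asked what the peptide changed in fatty acid loaded cells. None of the genes that the fatty acids had raised was called between these groups in edgeR's test, and intervals were wide for the scarce ones. Plin2, summed over 3 transcripts in this table, was at 10.4 ± 4.62 CPM with Ang(1-7) and 12.9 ± 2.90 without (mean ± SD, n = 3 per group, log2 change −0.31 ± 0.38, 95% interval −1.16 to 0.54). Cpt1a, summed over 4 transcripts, was at 8.03 ± 0.70 and 9.05 ± 2.07 (−0.17 ± 0.29, −0.82 to 0.47). Log2 changes were −0.07 ± 0.16 for Cxcl5, −0.12 ± 0.22 for Cxcl1, 0.08 ± 0.10 for Ccl2, 0.12 ± 0.12 for C3, −0.18 ± 0.12 for Acot1 and, for Scd1, which the fatty acids had lowered, 0.23 ± 0.12. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 0 of 9261 genes were called, and the lowest adjusted p was 0.965. An unadjusted p under 0.05 was found for 236 genes where chance gives 463, limma-voom called 0 genes and DESeq2 3, and the groups did not overlap in 11% of genes where chance gives 10%. Without Ang(1-7) 2, edgeR also called 0 genes, of 9662. Log2 changes with 95% intervals were then 0.11 (−0.05 to 0.27) for Cxcl5, 0.14 (−0.04 to 0.31) for Cxcl1 and 0.06 (−0.08 to 0.20) for Ccl2. Those of Plin2 (−0.51 to 0.56) and Cpt1a (−0.71 to 0.51) stayed wide.

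The 3 genes of DESeq2, which were chosen after their values were seen, were Gfap, S100a11 and Nsun3. S100a11, a calcium-binding protein gene, had 3102, 3237 and 2567 counts in PA/OA and 4279, 6220 and 7056 with Ang(1-7) (log2 change 0.96, DESeq2 adjusted p = 0.0175), and Nsun3, a mitochondrial tRNA methyltransferase gene, had 225, 265 and 266 against 502, 578 and 495 (1.05, DESeq2 adjusted p = 0.0298). Gfap (DESeq2 adjusted p = 0.0175) is the astrocyte gene with 12, 888 and 378 counts given above. Without Ang(1-7) 1, edgeR called 18 genes, of which all but S100a11 and S100b were at 0 in each PA/OA library, Nefl and Gfap among them. Acsl3, an acyl-CoA synthetase gene and the lipogenesis member of lowest p, had 212, 195 and 230 counts in PA/OA and 240, 1036 and 274 with Ang(1-7) (1.25 ± 0.51, adjusted p = 0.965), and its log2 change was 0.27 without Ang(1-7) 2. Simulated counts made from these libraries recovered 8.96% of genes changed 1.5-fold, 31.3% of those changed 2-fold and 74.2% of those changed 4-fold. Most differences under 2-fold would thus be missed at the simulated spread. That spread was the same in all libraries for a gene, so Ang(1-7) 2 was not simulated as a library that stood apart. The changed genes had a mean of at least 50 counts, so these shares do not cover scarcer genes.

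Of 23 lists with at least 5 measured members, 0 passed camera, 2 had an unadjusted p under 0.05, and fry passed 0. The lowest adjusted p was 0.951 with an estimated correlation. The lipid droplet list came closest, with a fitted change below 0 in 12 of its 13 genes, a median of −0.20, an unadjusted p = 0.0130 and an adjusted p = 0.299. Its lowest p values belonged to Cideb (0.78 ± 0.38), a droplet fusion gene, Lipe (−1.08 ± 0.64), the hormone-sensitive lipase, and Agpat2 (−0.65 ± 0.43), each with an adjusted p of 0.965. Immediate early genes had a median of −0.19 over 21 genes (unadjusted p = 0.0395, adjusted p = 0.423). In fatty acid oxidation the scarce Ehhadh had a fitted change of −1.50 ± 0.86, and the median was −0.03. In the renin-angiotensin list Agt (0.54 ± 0.45), Ctsa (0.38 ± 0.25) and Prep (−0.22 ± 0.14) had the lowest p, and in cholesterol synthesis Tm7sf2 (−0.47 ± 0.23) and Msmo1 (0.39 ± 0.21) were among those of lowest p, as were Mid1ip1 (−0.39 ± 0.20) and Fads1 (−0.50 ± 0.25) in lipogenesis. Sterol efflux and interferon genes, with 7 and 8 measured members in this table, had a camera adjusted p = 0.795 and 0.954. Over the lists of lipogenesis, cholesterol, inflammation, interferon, autophagy, glycolysis and cholangiocyte markers the median, mean and test differed in sign. With 1 library left out, log2 changes ran from −1.81 to −0.80 for Ehhadh (the latter without PA/OA 2), 0.078 to 0.55 for Msmo1 (the former without Ang(1-7) 2), −1.60 to −0.83 for Lipe, −1.06 to −0.27 for Agpat2, −0.67 to −0.23 for Tm7sf2, −0.65 to −0.27 for Fads1 and 0.18 to 0.53 for Ctsa, none of them called. The log2 change of Plin2 was 0.03, that of Agt −0.05 and that of Pdk4 0.27 (against −0.20 ± 1.22) without Ang(1-7) 2, and that of Angptl4 was −0.08 (against 0.03 ± 0.15) without PA/OA 3. Without each of PA/OA 1, 2 and 3 the stellate cell list reached 5 members and passed (adjusted p = 0.00477, 0.00250 and 0.0175), as it (6.94e-09) and the macrophage list (0.00727) did without Ang(1-7) 1. The expression filter was repeated in each of these fits, so members high only in Ang(1-7) 2 and 3 could enter through it. These passes therefore decide nothing about an effect of the peptide.

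The comparison of Ang(1-7) with control asked how cells given both the peptide and the fatty acids stood against untreated ones. The genes raised here were again chemokines and C3. Cxcl5 went from 239 ± 9.73 to 1540 ± 345 CPM (mean ± SD, n = 3 per group, 6.44-fold), C3 from 45.7 ± 2.08 to 231 ± 19.7 (5.05-fold) and Cxcl3 from 18 ± 0.309 to 79.4 ± 7.59 (4.41-fold). Aldh1a1, a retinaldehyde dehydrogenase gene, rose 2.76-fold from 502 ± 17.0 to 1384 ± 133. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 15 of 6134 genes rose and 0 fell, 10 of them at least 2-fold. An unadjusted p under 0.05 was found for 915 genes where chance gives 307, and the groups did not overlap in 26.5% of genes where chance gives 10%. Without Ang(1-7) 2, the library that stood apart, 624 genes were called (320 higher). The count was 4 without each of controls 1, 2 and 3, 32 without Ang(1-7) 1 and 7 without Ang(1-7) 3, and DESeq2 called 259 genes (161 higher) and a fit of all 9 samples 95 (61 higher).

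Other risen genes named by the rule were Ccl7 (log2 change 2.51 ± 0.31, adjusted p = 0.0226), S100a11 (1.34 ± 0.18, adjusted p = 0.0363), Nt5e, the ectonucleotidase CD73 (1.30 ± 0.19, adjusted p = 0.0459), Ms4a4d (1.25 ± 0.12, adjusted p = 0.00564), Ptgs2 (0.97 ± 0.10, adjusted p = 0.00627) and Ccl2 (0.89 ± 0.10, adjusted p = 0.00963). A further 4, named after their values were seen, were Apob (1.07 ± 0.10), Hpx, the heme-binding hemopexin (0.78 ± 0.11), Slfn2 (0.86 ± 0.09) and Tnip3 (1.06 ± 0.15). The calls of Cxcl5, C3, Cxcl3 and Aldh1a1 were kept with each of the 6 libraries left out. Without controls 1, 2 and 3 in turn, the adjusted p was 0.203, 0.119 and 0.0840 for Ccl7, 0.337, 0.189 and 0.280 for S100a11, 0.382, 0.119 and 0.280 for Nt5e, 0.10, 0.0990 and 0.0827 for Ms4a4d, 0.10, 0.115 and 0.114 for Ptgs2, and 0.0935, 0.119 and 0.165 for Ccl2. Without Ang(1-7) 3 it was 0.0808 for Ccl7, 0.134 for S100a11, 0.204 for Nt5e and 0.0664 for Ccl2, and with DESeq2 size factors it was 0.0501 for Nt5e. Apob lost its call without each control (0.0827 to 0.0935), Slfn2 without each control or Ang(1-7) 3 (0.0664 to 0.139), and Hpx (0.0834 to 0.349) and Tnip3 (0.0835 to 0.337) in every fit but that without Ang(1-7) 2. Lcn2 (6.33, adjusted p = 0.0514) and Saa3 (4.32, adjusted p = 0.0559) were not called with all 6 libraries. Without Ang(1-7) 2 both were called (5.95, adjusted p = 0.000257, and 4.49, adjusted p = 3.93e-05), and Lcn2 was also called without Ang(1-7) 1 (0.0458), with ranges over the libraries left out of 0.000257 to 0.358 and 3.93e-05 to 0.472. The log2 change of Lcn2 was 8.54 without control 1, and that of Saa3 5.10 without control 3. Plin2 (0.70 ± 0.46, adjusted p = 0.494) was not called, and Angptl4 (0.26 ± 0.11), Hmgcs1 (0.43 ± 0.45), Scd1 (−0.14 ± 0.11) and Ddit3 (0.09 ± 0.28, −0.07 without control 2) were not either.

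Of 18 measured inflammation genes, 4 rose and 0 fell, and 8 rose adjusted over the list alone (median 0.90, camera adjusted p = 3.48e-09, adjusted p = 0.0818 with an estimated correlation). Ribosomal protein genes fell as a list (29 measured, 0 called in edgeR's test, 3 fallen adjusted over the list alone, median −0.28, camera adjusted p = 0.000573, adjusted p = 0.215 with an estimated correlation), as did oxidative phosphorylation genes (31 measured, 0 called, 0 adjusted over the list alone, median −0.20, camera adjusted p = 0.000573, adjusted p = 0.196 with an estimated correlation). Rps19 (−0.87 ± 0.21, adjusted p = 0.139), Rpl30 (−0.76 ± 0.20, adjusted p = 0.173) and Rpl18 (−0.54 ± 0.10, adjusted p = 0.0984) had the lowest p of the ribosomal genes and Ndufv1 (−0.48 ± 0.17), Ndufb10 (−0.37 ± 0.12) and Ndufs3 (−0.30 ± 0.10) of the others. Fatty acid oxidation genes rose as a list (19 measured, 0 called, 5 risen adjusted over the list alone, median 0.25, camera adjusted p = 0.0397, adjusted p = 0.234 with an estimated correlation), with Acot1 at 0.75 ± 0.12 (adjusted p = 0.0514), Acot2 at 0.80 ± 0.21 and Cpt1a at 1.77 ± 0.48 (adjusted p = 0.173 each). The matrix list rose (19 measured, 1 called, 5 risen adjusted over the list alone, median 0.37, camera adjusted p = 0.0397, adjusted p = 0.234 with an estimated correlation). With the replicate number as a block only 1 of the 3 risen lists passed. With the length and GC correction the medians of the ribosomal protein and oxidative phosphorylation lists were −0.093 and −0.15, and both still passed (adjusted p = 0.0429 each). The oxidation list was not called without control 1 (adjusted p = 0.0874), control 2 (0.108), control 3 (0.0655) or Ang(1-7) 2 (0.120, range 0.0284 to 0.120 over the libraries left out), nor the matrix list without control 1 (0.0989), control 3 (0.108), Ang(1-7) 1 (0.0923) or Ang(1-7) 2 (0.0842, range 0.0356 to 0.108). Of the 21 lists tested 5 passed, 0 with an estimated correlation, and fry passed 8, these 5 and the unfolded protein response (higher, adjusted p = 0.00750), heat shock (higher, 0.0189) and lipogenesis (lower, 0.0429) lists. Unfolded protein response genes came next (7 of 19 risen adjusted over the list alone, camera adjusted p = 0.0910, 0.0429 with the length and GC correction). Over the cholesterol, antioxidant, glycolysis and immediate early lists the median, mean and test differed in sign.

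The library Ang(1-7) 2 moved several of these values. Without it Acot1 was called (log2 change 0.84, adjusted p = 9.17e-06), as were Scd1 (−0.24, adjusted p = 0.0246) and Rps19 (−0.73, adjusted p = 0.00909), while Cpt1a (1.57, adjusted p = 0.0877) and Plin2 (1.02, adjusted p = 0.116) were not. In all, 13 of the 39 named genes gained a call without it, and 0 lost one. The fit with library quality weights, chosen after the data were seen, gave Ang(1-7) 2 a weight of 0.133 and called 608 genes (334 higher). Vim was at 9893 CPM in Ang(1-7) 2 and at 6226 and 6316 in Ang(1-7) 1 and 3.

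The design also asks which changes of the fatty acids were moved back by Ang(1-7). Of the 314 genes changed by PA/OA, 0 were called in the opposite direction in the comparison of Ang(1-7) with PA/OA, in which edgeR called 0 genes and DESeq2 3 as given above, and 236 genes had an unadjusted p under 0.05. The fitted change of 131 of the 314 (41.7%) was opposite, against 57.4% (52.0% to 61.7%) in 40 simulations in which the fatty acid effects were left as they were and the groups shared the PA/OA libraries. Against control, 309 of the 314 kept their sign with Ang(1-7) and the median ratio of the log2 changes was 1.10 (simulated 0.947, 0.911 to 0.990), or 1.04 without Ang(1-7) 2. Cxcl5 was at 2.76 against control with PA/OA and 2.69 with Ang(1-7), C3 at 2.23 and 2.34, Acot1 at 0.94 and 0.75, and Cpt1a at 1.75 and 1.77. Some of the 131 lay well nearer to control with Ang(1-7): Ttr at −1.79 and −0.84, Sult1d1 at −1.44 and −0.69, Tmem252 at −0.90 and 0.008, and Plin2 at 1.30 and 0.70. Without Ang(1-7) 2 the latter values were −1.50, −0.91, −0.32 and 1.02. Others of the 314 lay farther from control: Ccl7 at 1.97 and 2.51 (2.30 without Ang(1-7) 2), B2m at 0.29 and 0.84, and Ugt1a6a at 1.22 and 1.88. B2m and Ugt1a6a were named after their values were seen. In edgeR's test of Ang(1-7) against PA/OA, 0 of the 175 raised genes had an unadjusted p under 0.05 in the opposite direction and 2 in the same one. For the 139 lowered genes these counts were 1 and 8. The share of equal sign, 98.4%, stood beside 84.4% (81.7% to 87.6%) for the 314 genes of lowest p in simulations with no effect and the same controls, and beside 97.3% (95.5% to 98.4%) with the fatty acid effects left as they were. Across 6212 genes, which are not independent replicates, the changes of PA/OA against control and of Ang(1-7) against PA/OA correlated at r = −0.136 (simulated −0.436, −0.462 to −0.415, with no effect and −0.376, −0.416 to −0.346, with the fatty acid effects left as they were), and their covariance was −0.0179 (simulated −0.0451 with no effect and −0.0452 with those effects). This r was −0.235, −0.233 and −0.252 without PA/OA 1, 2 and 3 and −0.222 in a fit of all 9 samples. The simulations gave the 3 Ang(1-7) libraries the same spread per gene and no change to uncalled genes. The observed r and covariance lay outside the range of both kinds of simulation. The opposite share and median ratio lay outside that with the fatty acid effects left as they were. Whether Ang(1-7) strengthened or weakened the changes therefore cannot be read from these simulations.

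Of the 15 genes called for Ang(1-7) against control, 14 were called for PA/OA too, all higher, and S100a11 was not. Independent lists would share 0.435 higher genes, and simulations with the same controls shared 0 genes with no effect and 60.5 (46.0 to 76.1) with the fatty acid effects left as they were. Without Ang(1-7) 2, 243 of 619 called genes were shared in the same direction (134 higher and 109 lower) and 0 in the opposite one, against 9.13 higher and 7.00 lower for independent lists, 0 in simulations with no effect and 65.7 (51.0 to 84.1) with the fatty acid effects left as they were. The simulations with those effects called 232 genes (207 to 251) in PA/OA against control, below the 314 observed, and did not model Ang(1-7) 2 as a library that stood apart, so their overlaps are no measure of what unchanged effects would share. The 3 controls were too few to be split, so part of the overlap may come from the controls that both comparisons share.

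**Figure D4:**
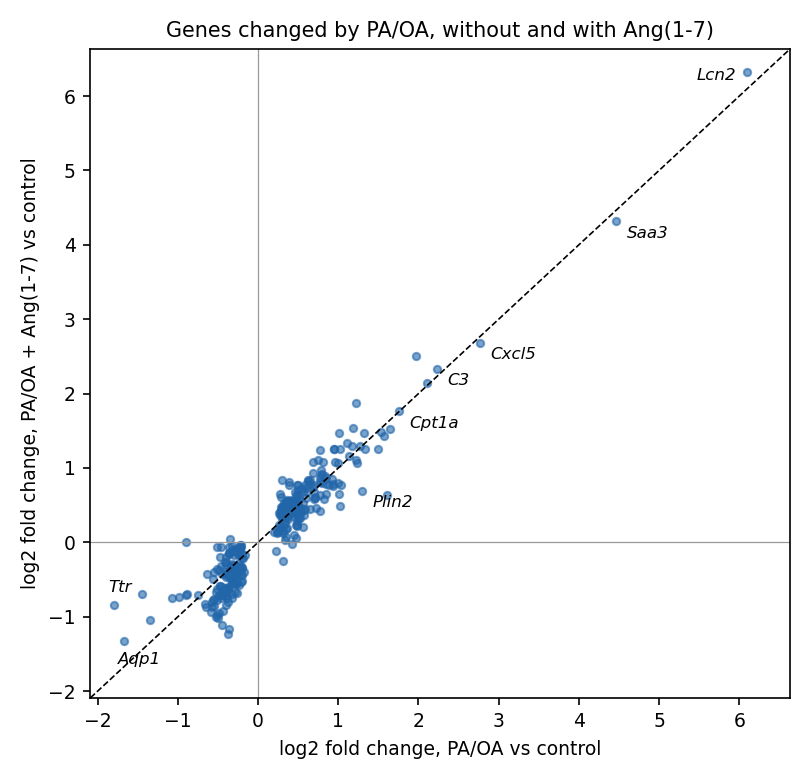
Log2 fold change against control with PA/OA (x axis) and with Ang(1-7) and the fatty acids (y axis), 1 point for each of the 314 genes called in PA/OA against control, with the line of equal change dashed. On both axes 309 of the 314 points have the same sign.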

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

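Transcripts tested without summing, library quality weights, the length and GC correction, Ang(1-7) 1 as the 1 treated library and the fits without marker genes were chosen after seeing the data. For genes changed in PA/OA against control (PA_OA vs control, 314), the DESeq2 Wald test gave 533, all 9 samples in 1 fit 31, a log2 change of at least 1 33, an adjusted p under 0.01 100, and leaving out 1 library 99 to 397 (99 without control 1, 134 without PA/OA 3, 147 without PA/OA 2 and 200 without control 3). The other counts for this comparison lay between 229 (149 higher), with the length and GC correction, and 357, with quality weights. For genes changed in Ang(1-7) against PA/OA (PA_OA_Ang17 vs PA_OA, 0), DESeq2 gave 3 and leaving out 1 library 0 to 18 (18 without Ang(1-7) 1), and every other alternative run gave 0. For genes changed in Ang(1-7) against control (PA_OA_Ang17 vs control, 15), DESeq2 gave 259, all 9 samples 95, quality weights 608, Ang(1-7) 1 as the 1 treated library 229, an adjusted p under 0.01 9, and leaving out 1 library 4 to 624 (4 without each control, 7 without Ang(1-7) 3, 32 without Ang(1-7) 1 and 624 without Ang(1-7) 2). The others gave 10 to 21. In the fit with a single treated library that library is assumed to vary like the controls. Pseudocounts for normalized values, considered in advance, were not run because the values are counts. The cause of these shifts was not tested, except that stricter thresholds pass fewer genes, that fewer samples enter a fit with a library left out and that Ang(1-7) 2 entered with a low weight or not at all in the fits with 608 and 624 genes.

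For gene lists changed, an estimated correlation left 0 in PA/OA against control (PA_OA vs control, 6) and 0 in Ang(1-7) against control (PA_OA_Ang17 vs control, 5), where fry gave 8. Leaving out 1 library gave 4 to 7, 0 to 2 and 3 to 5 lists in the 3 comparisons. It gave 3 in the last without control 1, control 3 or Ang(1-7) 2. In Ang(1-7) against PA/OA (0) it gave 1 without each PA/OA library and 2 without Ang(1-7) 1, where the stellate cell list then reached 5 members. Members high only in Ang(1-7) 2 and 3 could enter through the repeated filter, so these passes decide nothing. The correlation of fold changes (−0.136) was −0.222 with all 9 samples and −0.252 to −0.0985 with 1 library left out (−0.235, −0.233 and −0.252 without PA/OA 1, 2 and 3). The count of genes moved back was 0 under every alternative run. It could hardly differ, since of those fits only that without Ang(1-7) 1 called any gene between Ang(1-7) and PA/OA (18). The DESeq2 test was not run for this count. Signs turned for genes that were not called, with ranges over the libraries left out of −0.070 to 0.56 for Hmgcs1 (−0.031 without control 1, −0.070 without PA/OA 3) and −0.31 to 0.068 for Ddit3 (0.068 without PA/OA 3) in PA/OA against control. They also turned for Agt (−0.048 to 0.85), Pdk4 (−0.70 to 0.27) and Plin2 (−0.57 to 0.025) without Ang(1-7) 2 and Angptl4 (−0.076 to 0.19) without PA/OA 3 in Ang(1-7) against PA/OA, and for Ddit3 (−0.068 to 0.18, the former without control 2) in Ang(1-7) against control. The cause was not tested.

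Whether the replicate numbers pair the samples could not be settled with 3 samples per group. The correlation of deviations of samples with the same number was small, from −0.0989 to 0.0470. The best partner was the sample with the same number for 3 of 3 in PA/OA against control, 0 of 3 in Ang(1-7) against PA/OA and 1 of 3 in Ang(1-7) against control. With the replicate number as a block, 303, 0 and 10 genes and 5, 0 and 3 lists were called, the fatty acid oxidation list being lost in PA/OA against control (adjusted p = 0.0608). In Ang(1-7) against control 1 risen and 2 fallen lists passed with the block, against 3 risen and 2 fallen without it. The correlation of fold changes was −0.114. Cpt1a and Fasn lost their call in PA/OA against control and Nt5e and Ccl2 in Ang(1-7) against control. Few counts limit genes such as Pdk4, Lcn2 in control and Hmgcs1. Hmgcs1 was listed through 1 of its 3 RefSeq transcripts, so its few counts need not come from depth. A gene under the lowest listed level was not measured here. For most listed genes the spread between samples, above all with Ang(1-7) 2, limited what could be called. In Ang(1-7) against PA/OA, however, 0 genes and 0 lists were called without that library too.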

Other observations

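The complement, retinoid and histone lists and the tests of class ratios, of induction, of the count without Ang(1-7) 2 and of S phase were chosen only after the result was seen. Of 6 complement genes measured in PA/OA against control, 3 rose, 0 fell and 3 were not called in edgeR's test, with no test of the list. Those that rose were C3, C1ra, a protease of the classical pathway (log2 change 0.64 ± 0.14, adjusted p = 0.0114), and C2, which forms the C3 convertase (0.60 ± 0.15, adjusted p = 0.0194). C1ra was not called without control 2 (adjusted p = 0.0513), nor C2 without control 2 (0.0777), control 3 (0.0979) or PA/OA 3 (0.0747). Of 9 retinoid genes, likewise not tested as a list, 3 rose, 0 fell and 6 were not called. Aldh1a1 rose by 1.32 ± 0.06 (adjusted p = 8.36e-12), Aldh1a7 by 1.54 ± 0.25 (adjusted p = 0.000729) and Rdh10, which oxidises retinol, by 0.56 ± 0.06 (adjusted p = 8.32e-06). In Ang(1-7) against control 1 of 6 complement genes (C3) and 1 of 9 retinoid genes (Aldh1a1) rose, and in Ang(1-7) against PA/OA 0 of 10 and 0 of 12 were called, where DESeq2 called 3 genes of any kind and 236 genes had an unadjusted p under 0.05.

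Of 64 histone genes measured in PA/OA against control, 32 fell and 0 rose in edgeR's test, 61 had a fitted change below 0 and the median log2 change was −0.36, or −0.37 with DESeq2 size factors and −0.20 with the length and GC correction. The count of lower ones was 8 without control 1, 20 without PA/OA 2 and 8 without PA/OA 3. In Ang(1-7) against control 63 of 64 were below 0 with a median of −0.64 (−0.35 with the length and GC correction) and 0 were called (56 lower without Ang(1-7) 2, 7 without Ang(1-7) 1), and in Ang(1-7) against PA/OA the median of 65 was −0.25 (−0.15 with the correction) with 0 called. Reads shared between near-identical histone genes make single members uncertain.

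Nervous system transcripts were far higher in Ang(1-7) 2 and 3 than in the other libraries of the table. Induction by the peptide in each treated culture is argued against, since the upper 95% limit of the markers in Ang(1-7) 1 was 4.25% of the mean of the other two. RNA of nervous tissue in these libraries is a candidate explanation: it would keep 1 ratio between them for all classes, and the ratios of Ang(1-7) 3 over Ang(1-7) 2 were 0.561 for neuron, 0.493 for astrocyte and 0.644 for oligodendrocyte markers, the largest 1.31 times the smallest. Of 10 further abundant nervous system genes with 1 transcript and under 5 CPM in PA/OA, 90% (9, with the exception of Bex2) were higher in both libraries than in the other 4, which decides nothing, because 8 of the 10 would fall under the lowest listed mean count without these libraries and 3 other such genes were not listed. Where such RNA could have entered, and whether these cultures themselves made the transcripts, was not tested.

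Ang(1-7) 2 stood apart in many genes. Of 6033 genes with a value in all 9 libraries and a mean of at least 50 counts, 1175 were off by more than 2-fold in it (77 to 220 in the other 5), and 75.8% of these were lower, so added nervous tissue RNA alone is argued against. Length and GC content explained 4.04% of the variance of its deviations, which argues against that trend. Low library complexity stays open. The slope of excess variance against abundance was 0.743 (SE 0.047). It was above the limit of 0.7, set in advance for arguing against low complexity, by less than 2 SE, a margin added after the value was seen. The other 5 libraries had slopes of 0.274 to 0.424, under the limit of 0.5 set in advance for low complexity. These limits thus do not mark low complexity, and the slope decides nothing. Without this library 624 genes were called against control, so it may alone account for the low count of 15, and no biological explanation was tested, since the design gives it the same treatment as its group.

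The small fall of ribosomal protein, oxidative phosphorylation and histone genes with PA/OA may be a matter of transcript length in part. The longest GENCODE transcripts of these genes are short (median 1120, 1661 and 536.5 bases against 3124.5). The log2 change rose with that length across other genes (Spearman rho = 0.262 across genes, which are not independent replicates). After the length and GC correction 30.2%, 44.0% and 55.0% of the median changes were left, and the genes called lower went from 10 to 5, from 5 to 1 and from 32 to 7. The ribosomal protein and oxidative phosphorylation shares met the level set in advance for the trend as the cause, yet both lists still passed (camera adjusted p = 0.0227 and 0.00501, though before the correction neither passed with an estimated correlation, adjusted p = 0.295 and 0.190), so whether the trend is the whole cause is left undecided. Fewer cells in S phase stays open for the histone genes, since the cell cycle list had a median of −0.083 with 10 of 22 members above 0, which decides nothing. An effect of the fatty acids on these genes and a difference in RNA recovery between the groups cannot be told apart here, because such a difference would coincide with the groups.

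Each set of 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In PA/OA against control the real split gave 314 genes and 6 lists and the highest other split 0 and 2, with 1 of 10 splits as large for each. In Ang(1-7) against PA/OA all 10 splits gave 0 genes and 0 lists, the real one included. In Ang(1-7) against control the real split gave 15 genes and 5 lists and the highest other 0 and 1, with 1 of 10 as large for each.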
